A study of Homo sapiens with 4 samples.

How the data were processed

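RNA of cells that the sample titles name as Huh7, a human hepatocellular carcinoma line, was measured on 4 single-colour Agilent expression arrays. Each of the 4 groups had 1 array: control siRNA, MEF2D siRNA, control lentivirus and lentivirus with a MEF2D shRNA. Total RNA was amplified and labelled with Cy3, per the labels. The siRNA pair lay on 1 slide and the lentivirus pair on another slide with its own scan, so delivery method, slide and scan cannot be told apart.

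The deposited array files hold fluorescence intensity per spot, in arbitrary units on a linear scale, from Agilent Feature Extraction 10.7, per the file headers and the submitters' processing notes. The processed intensity is background-subtracted and spatially detrended by that software, with no scaling between arrays, per the file headers. The deposited series table holds log2 values, and its normalisation is not stated. Of the sorted values of the siRNA pair there, 98.3% lay within 0.001 of each other, as after quantile normalisation of this pair alone. The deposited log2 values of the lentivirus pair were the processed signals moved by 1 constant per array, −0.23 for the control and 0.23 for MEF2D shRNA, which gave both the same 75th percentile.

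Each array had 45015 spots, of which 43376 were not controls. Spots well above background, by the scanner software's own call, made up 73.5% on the control siRNA array, 73.8% on the MEF2D siRNA array, 66.3% on the control lentivirus array and 62.2% on the MEF2D shRNA array. No spot was saturated (0 on each array). Slopes of the spike-in signals against their known amounts on log10 scales ran from 0.992 to 1.05. Probes printed 10 times and bright on an array had a median SD between spots of 0.05 to 0.08 log2 units. The number of arrays, 1 per group, limits the precision: the standard error printed beside a log2 fold is that of the scanner software's preset error model, which covers the spot signals and leaves out the variation between cultures.

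Processed signals were log2-transformed, and the 75th percentile over the array's non-control probes was subtracted. Spots that the scanner software marked as outliers, for the spot itself or for its local background, were left out (341, 508, 429 and 278 spots, in the order above). At first only marks of the spot itself were used, and the marks of the local background were added after 3 very high folds had been seen on such spots. Spots of a probe were averaged, and 1 probe per gene was used, the one with the highest mean over the 4 arrays. Of 41000 probes, 27229 matched 1 gene symbol through the RefSeq accession in the files and a RefSeq gene table of assembly GRCh38.p14. The files annotate the probes on GRCh37, so no coordinates are given. The accession of 7294 probes differed between the slides' annotations. For 21 probes both gave a symbol and the symbols differed. There were 18210 genes with a symbol and 17927 with values on 4 arrays, after 987 probes had lost their value on at least 1 array. List members under older symbols were matched through synonyms only where the symbol was not itself in use, a rule added after wrong matches had been seen.

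Folds are silenced minus control within a delivery method. With 1 array against 1 no p-value was given, and a gene counted as at least 2-fold different when its absolute log2 fold reached 1 and it was well above background on both arrays. Genes above background on 1 array of a pair were counted apart. A gene above background on the silenced array alone was given a lower bound of its fold, against the level that the control array's background call needs. The count of genes at least 2-fold different the same way in both pairs was set beside the overlap of independent lists. The only fit with residual degrees of freedom used limma 3.58.1 in R 4.3.3 on the 4 arrays, with silencing and delivery method as terms. It had 1 residual degree of freedom per gene, moderated over genes by eBayes (prior degrees of freedom 3.02, prior SD 0.232). Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05 over 14335 genes well above background on at least 2 arrays. Any difference between the effects of the 2 delivery methods counts as error in this fit, and that difference itself was not tested. Tables were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9.

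Gene lists were fixed before the data were examined, as were the comparisons and the rule for named genes. The lists covered the MEF2 family, G2/M inhibitors, G2/M promoters, G1/S and DNA replication, p53 targets, MEF2 targets and immediate-early genes, apoptosis regulators, interferon-stimulated genes, NF-kB and inflammatory genes, the unfolded protein and amino acid stress response, hepatocyte genes, oncofetal liver and progenitor genes, cholesterol synthesis, fatty acid synthesis and storage, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, epithelial and mesenchymal genes, RNA interference machinery, and markers of fibroblast and stellate, leukocyte and endothelial cells. A member counted as measured when well above background on at least 2 arrays. Each list's median fold was placed among 10000 random lists of the same size matched on mean expression, as a percentile that describes these arrays. Members shared between lists count in each. Named genes are MEF2D and the cell cycle genes CDK1, CDC25C, CCNB1, CDKN1A, GADD45A, GADD45B and RPRM, then the 10 highest and 10 lowest folds per pair among genes above background on both arrays. The rule also took the 10 highest and 10 lowest by the smaller of both folds among genes on 4 arrays, and up to 4 members per list with the highest absolute mean fold. Other names are said to have been chosen after their values were seen.

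Alternatives were normexp background correction (offset 50) with quantile normalisation on the median signals, each array's median as its scale, quantile normalisation of processed signals, the deposited table, no filter on dim probes, the mean of a gene's probes, a 1.5-fold threshold, genes above background on 4 arrays, list means, no method term, eBayes with an intensity trend, a threshold of 0.10, and each pair left out. The planned mean signals are not in the files, so median signals took their place in normexp. Keeping spots marked for their local background alone was added after the data had been seen.

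The procedure was tested on simulated data with the spread of the real fit, for MEF2D silencing over both methods (14335 genes). Limma called 0 of 70 genes made 2-fold different, 2 of 70 made 4-fold different, 53 of 60 made 16-fold different and 4 of 14135 left unchanged. The 16-fold genes were added to the simulation after the smaller sizes had given 0 calls. At an unadjusted p under 0.05 the shares were 90.0%, 100%, 100% and 4.85%. Among unchanged genes, 740 of 13830 (5.35%) reached 2-fold in the simulated siRNA pair and 631 of 12083 (5.22%) in the simulated lentivirus pair. The simulated noise came from the fit, where any difference between the methods counts as error, so these shares are not rates of chance for the real pairs. Of 20 simulated lists moved by 0.5 in the siRNA pair 20 left the central range of random lists, as did 2 of 20 lists not moved. The 13771 probes without a symbol were kept out of the gene comparisons.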

Results

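Gene expression was measured in cells that the sample titles name as Huh7, a human hepatocellular carcinoma line. The cells were labelled as given MEF2D siRNA by transfection or MEF2D shRNA by lentivirus, each beside its own control. Arrays are called silenced by their labels alone. There was 1 array per group and 4 arrays in all, so no value has a spread between replicate cultures. The 75th percentile of the processed signal was 572 on the control siRNA array, 676 on the MEF2D siRNA array, 769 on the control lentivirus array and 562 on the MEF2D shRNA array. Genes well above background on 4 arrays numbered 12030. The scanner software put the spike-in spread of the control lentivirus array, a median CV of 10.8%, outside its accepted range.

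The labels name MEF2D, a transcription factor of the MEF2 family, as the silenced gene. MEF2D (NM_005920) had a log2 fold of −0.36 after siRNA and −0.09 after shRNA, each with a scanner standard error of 0.20, so the shRNA value was smaller than its own error and this probe did not show the target lowered on that array. Both values of this probe were negative under each of the 4 other scalings, and a dimmer MEF2D probe gave −0.15 and −0.49. MEF2D had a mean of −0.23 over both methods, and limma gave an adjusted p of 0.735. MEF2A, another member of the family, was at 0.66 and 0.38. The MEF2 family list had 3 measured members and medians of −0.08 and 0.38, the latter 0.0061 with normexp, and 0 of them passed limma over all genes or adjusted over the list alone.

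The series asks how MEF2D acts on the cell cycle at the G2/M transition. GADD45A and GADD45B, stress-induced growth arrest genes, were higher in both silenced arrays, with log2 folds of 1.34 and 1.26 after siRNA and 0.83 and 0.78 after shRNA. CDK1, the mitotic kinase, had −0.31 and 0.17, and its partner CCNB1 had −0.28 and 0.19. CDC25C, the phosphatase that activates CDK1, had −0.12 after siRNA and 0.56 after shRNA. The shRNA values of CDK1 and CCNB1 and the siRNA value of CDC25C were smaller than their scanner standard errors of 0.20. CDKN1A, the kinase inhibitor p21, was at −0.04 and 0.12 on its brightest probe, while a dimmer probe gave 0.55 after siRNA. RPRM, a p53-induced inhibitor of G2/M, was above background only on the MEF2D siRNA array, at least 14.9-fold higher than its control, on a single probe in 1 spot, and was above background on neither lentivirus array. That bound holds for the main values, and with normexp the log2 fold of RPRM was 1.61.

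**Figure D1:**
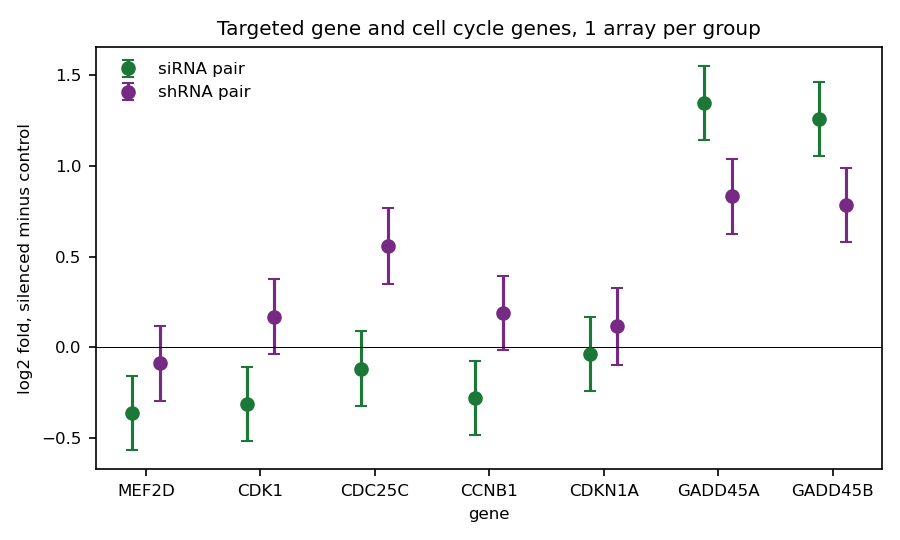
Log2 folds (vertical axis, silenced minus control) of MEF2D and the cell cycle genes of the study in the siRNA pair (green) and the shRNA pair (purple), with bars of 1 scanner standard error and 1 array per group. GADD45A lies at 1.34 and 0.83 and MEF2D at −0.36 and −0.09, while CDK1, CCNB1 and CDC25C are negative after siRNA and positive after shRNA. The shRNA values of CDK1 and CCNB1 and the siRNA value of CDC25C are smaller than their bars, so their signs are not resolved.

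Of 19 measured G2/M inhibitors, 3 were at least 1.5-fold higher in both pairs and 0 lower in both, with medians of 0.27 after siRNA (0.11 with normexp) and 0.25 after shRNA. RBBP8, a DNA end resection factor, had 0.71 after siRNA and just under 2-fold after shRNA. CDKN1C, a kinase inhibitor, had −0.32 and −0.96. The 34 G2/M promoters had a median of −0.26 after siRNA and 0.13 after shRNA, at percentiles 0.01 and 99.0 of random lists, and 0 were at least 1.5-fold higher and 1 lower in both pairs. CDC25A, a phosphatase that starts S phase and mitosis, was at −0.87 and −0.72 and KIF20A, a mitotic kinesin, at −1.08 and −0.07. MKI67, the proliferation marker Ki-67, was at −0.89 and −0.40, the latter −0.23 with normexp. With limma, 0 members of either list passed over all genes and 0 adjusted over the list alone, where the lowest p was 0.102 for inhibitors and 0.600 for promoters. The series description states directions for such genes from these arrays, so the lists are not independent evidence of them.

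Genes of G1/S and DNA replication were mostly lower after siRNA, with 33 of 37 members below 0, 12 of them at least 1.5-fold, and a median of −0.40. In the shRNA pair the median was −0.04 and became positive under normexp and under quantile normalisation. CDC6, which loads the replicative helicase, had −1.27 and −0.43, MCM6, a helicase subunit, −0.58 and −1.19, and POLE2, a DNA polymerase subunit, −0.89 and −0.70. Of 25 p53 targets, 4 were at least 1.5-fold higher in both pairs and 1 lower in both, with medians of 0.05 and 0.11 and means of 0.18 and 0.19. These medians lay at percentiles 79.5 and 87.3 of random lists, inside their central range. The shRNA median was higher with the mean of a gene's probes. SESN2, PLK3 and TNFRSF10B, genes of stress and death receptor signalling, had 2.24, 1.57 and 1.31 after siRNA and 1.42, 1.11 and 1.27 after shRNA. SESN2 is also a member of the unfolded protein and amino acid stress response list. Limma passed 0 G1/S genes adjusted over the list alone (lowest p 0.214) and 3 p53 targets (lowest p 0.0363), and 0 of either over all genes.

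The siRNA pair asks which genes differ after transfected MEF2D siRNA. Among the highest, ASNS, asparagine synthetase, had a log2 fold of 4.20, the cystine transporter SLC7A11 4.10 and CTH, an enzyme of cysteine synthesis, 3.55. INHBE, a hepatokine subunit, had 3.89 and STC2, a secreted stress protein, 3.80. GSG1L, AZU1 and BEST1 had 3.87, 3.75 and 3.67, and 1.40, 1.81 and 1.36 with normexp. Their levels on the control array were −5.72, −4.91 and −5.69, where the lowest level called above background was −5.95. With normexp SLC7A11 and INHBE were at 2.88 and 2.78, and in the shRNA pair INHBE and CTH were at 0.51 and 0.33. Among the lowest, STON1 was at −3.47, PZP at −3.15, HS3ST5 at −2.95, the heat shock gene HSPA1A at −2.94 and TCN1 at −2.70, and with normexp these were −1.11, −1.07, −0.90, −2.72 and −1.09. At least 2-fold differences were seen for 616 of 14023 genes, 403 higher and 213 lower, and a further 590 genes were above background on 1 array only (330 on the silenced array). STON1, HS3ST5 and TCN1 were at 0.79, 0.64 and 0.63 in the shRNA pair, where they were not above background and where HS3ST5 and TCN1 turn negative with normexp. The count was 271 with normexp and 1404 without a filter on dim probes. In simulated data 5.35% of unchanged genes reached 2-fold, but the noise there includes any difference between the methods, so this is no rate of false calls.

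In the shRNA pair the lowest folds were those of G6PC1, the glucose-6-phosphatase of glucose release, at −3.98, SLC6A12, a betaine transporter, at −3.34, LGALS2, a galectin, at −3.21, and APOA1, the main HDL apolipoprotein, at −3.12. The next were VAV3, SMLR1 and the tight junction gene CLDN14 at −3.02, −2.88 and −2.86, and GC, the vitamin D carrier, at −2.81. BAAT, a bile acid conjugating enzyme, had −2.71 and SERPINF2, the plasmin inhibitor, −2.62. After siRNA G6PC1, APOA1, GC, BAAT and SERPINF2 had −0.55, −0.23, −0.53, −0.77 and −0.03, and with normexp −0.35, −0.079, −0.47, −0.26 and 0. The highest were ATF3, a stress-induced transcription factor, at 3.20, ANKRD24 at 3.08, TMEFF2 at 3.02 and CARF at 2.87. The other genes among the 10 highest were the metallothioneins MT1L, MT1E and MT1B at 2.68, 2.65 and 2.61, FES at 2.66, and TMEM190 and IMMP2L at 2.62 each. The metallothionein folds were −1.13, −1.17 and −1.13 after siRNA, and the near-identical transcripts of this family share much sequence. With normexp ATF3 was at 3.08, but ANKRD24, TMEFF2, CARF, FES, TMEM190 and IMMP2L were at 1.27, 1.28, 1.13, 0.97, 1.58 and 1.06, and SLC6A12, CLDN14, GC, BAAT and SERPINF2 at −1.82, −1.57, −1.47, −1.43 and −1.56. At least 2-fold differences were seen for 851 of 12252 genes, 464 higher and 387 lower. That count was 399 with normexp, where 221 of those genes were lower, and 2028 without a filter. A further 1011 genes were above background on 1 array only, 768 of them on the control. The lowest level called above background was −5.43 on the control and −4.77 on the silenced array, so the 768 can hold genes without a lower level.

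Asked over both methods, 99 of 12030 genes were at least 2-fold different the same way, 80 higher and 19 lower, where independent lists would share 14.7, and 16 went opposite ways (14.1 for independent lists). Among unchanged genes of the simulated data, 67 of 11868 reached 2-fold the same way in both pairs and 109 opposite ways. The simulated noise came from the limma fit, where real differences between the methods count as error. With 109 opposite ways against 16 on the real arrays, the simulation does not measure chance for these counts. ATF3 had 3.61 after siRNA and 3.20 after shRNA, TRIB3, a pseudokinase of the same stress pathway, 3.61 and 2.56, and PPP1R15A, which restores translation after stress, 2.20 and 2.01 (the latter 1.27 with normexp). AREG, an EGF receptor ligand, had 2.84 and 1.94, IL23A, a cytokine subunit, 1.86 and 1.99 (1.03 in each with normexp), JDP2, a bZIP repressor, 1.82 and 1.99, and HOXB9 1.97 and 1.93, where its siRNA value was 0.61 with normexp. Lower in both were the heat shock genes HSPA2 (−2.47 and −1.73), HSPA8 (−2.22 and −1.44) and HSPA1A (−2.94 and −1.33). So were TNFSF10, the death ligand TRAIL (−1.27 and −2.60), CLDN14 (−1.55 and −2.86, the former −1.02 with normexp), the iron exporter SLC40A1 (−1.31 and −1.34) and the Wnt inhibitor DKK3 (−1.33 and −1.63). Across these genes, which are not independent replicates, the folds of both methods had a Pearson r of 0.31 and a Spearman rho of 0.30, and 60.3% had the same sign. Without the filter on dim probes r was 0.13.

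**Figure D2:**
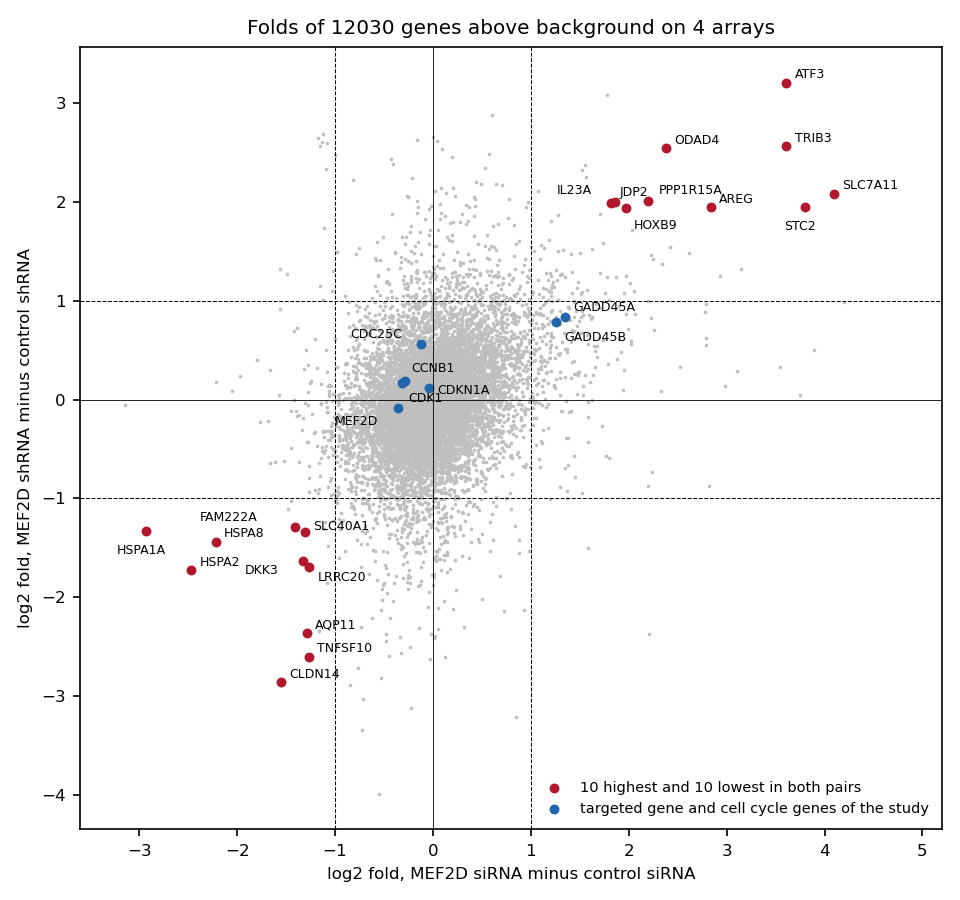
Log2 fold after MEF2D siRNA (horizontal axis) against log2 fold after MEF2D shRNA (vertical axis) for 12030 genes, 1 point each, with dashed lines at 2-fold and the 10 highest and 10 lowest in both pairs in red. ATF3 lies at 3.61 and 3.20 and TNFSF10 at −1.27 and −2.60, and the blue points of MEF2D, CDK1 and CCNB1 lie near the centre.

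Tested with limma over both methods, 0 of 14335 genes passed for silencing (lowest adjusted p 0.514, that of ATF3 among others), and 1344 had an unadjusted p under 0.05, 831 higher and 513 lower, where 717 would be expected by chance. Counts at the unadjusted threshold under other settings ran from 74 without the method term to 1658 with an intensity trend, and 0 genes passed the adjusted threshold except ATF3 with the trend (adjusted p 0.0354, mean log2 fold 3.41, higher in 2 of 2 pairs). The p-values set each gene's mean fold against the disagreement between the 2 pairs, moderated over genes. That disagreement may be technical or a real difference between the methods, and no spread between replicate cultures enters. In simulated data of this size limma found 2 of 70 genes that differed 4-fold and 53 of 60 that differed 16-fold.

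The unfolded protein and amino acid stress response list had 12 of 22 measured members at least 1.5-fold higher in both pairs and 0 lower in both, with medians of 1.38 after siRNA and 0.78 after shRNA, above all random lists in each pair. ASNS had 4.20 and 0.99, STC2 3.80 and 1.95, and TRIB3 3.61 and 2.56. MEF2 targets and immediate-early genes, the latter induced within minutes of a stimulus, had medians of 1.55 and 0.58. Of 18 members 8 were at least 1.5-fold higher in both pairs, while 3 were at least 1.5-fold lower after shRNA and 0 after siRNA. In this list KLF4 had 1.87 and 1.24 (1.02 and 0.76 with normexp) and NR4A3 1.08 (0.62 with normexp) and 2.11. NF-kB and inflammatory genes had 7 of 18 members at least 1.5-fold higher in both and medians of 0.71 and 0.83. Of these 18 members 2 were at least 1.5-fold lower after shRNA and 0 after siRNA. The chemokines CXCL1, CXCL8 and CXCL2 had 1.41, 1.67 and 1.52 after siRNA and 1.47, 0.97 and 0.89 after shRNA. Adjusted over the list alone, limma passed 11 stress genes (lowest p 0.00236), 7 immediate-early genes (0.00193) and 5 NF-kB genes (0.0317), all higher, and 0 of each over all genes. The lowest p of the stress and immediate-early lists is that of ATF3, a member of both, and the number of lists was not adjusted for.

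Of 22 genes of cholesterol synthesis, the SREBP2 programme, 8 were at least 1.5-fold lower in both pairs and 0 higher in both, while 3 were above 0 after siRNA and 2 after shRNA, with medians of −0.54 and −0.63, below all random lists. INSIG1, a sterol sensor partner, had −1.11 and −1.31, STARD4, a sterol carrier, −1.10 and −1.24 (−0.45 and −0.86 with normexp), IDI1 −1.21 and −0.91, and DHCR7, the last reductase of the pathway, −0.97 and −1.04. Limma passed 5 of them adjusted over the list alone (lowest p 0.0328) and 0 over all genes. Of 23 genes of hypoxia and glycolysis 4 were at least 1.5-fold lower in both and 1 higher, with medians of −0.28 and −0.46. PFKFB4, a regulator of glycolysis, had −1.66 and −0.64 and BNIP3, a mitophagy receptor, −0.74 and −0.84, while VEGFA, the angiogenic factor, had 1.53 and 1.09. Limma passed 0 of this list adjusted over the list alone (lowest p 0.0676).

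**Figure D3:**
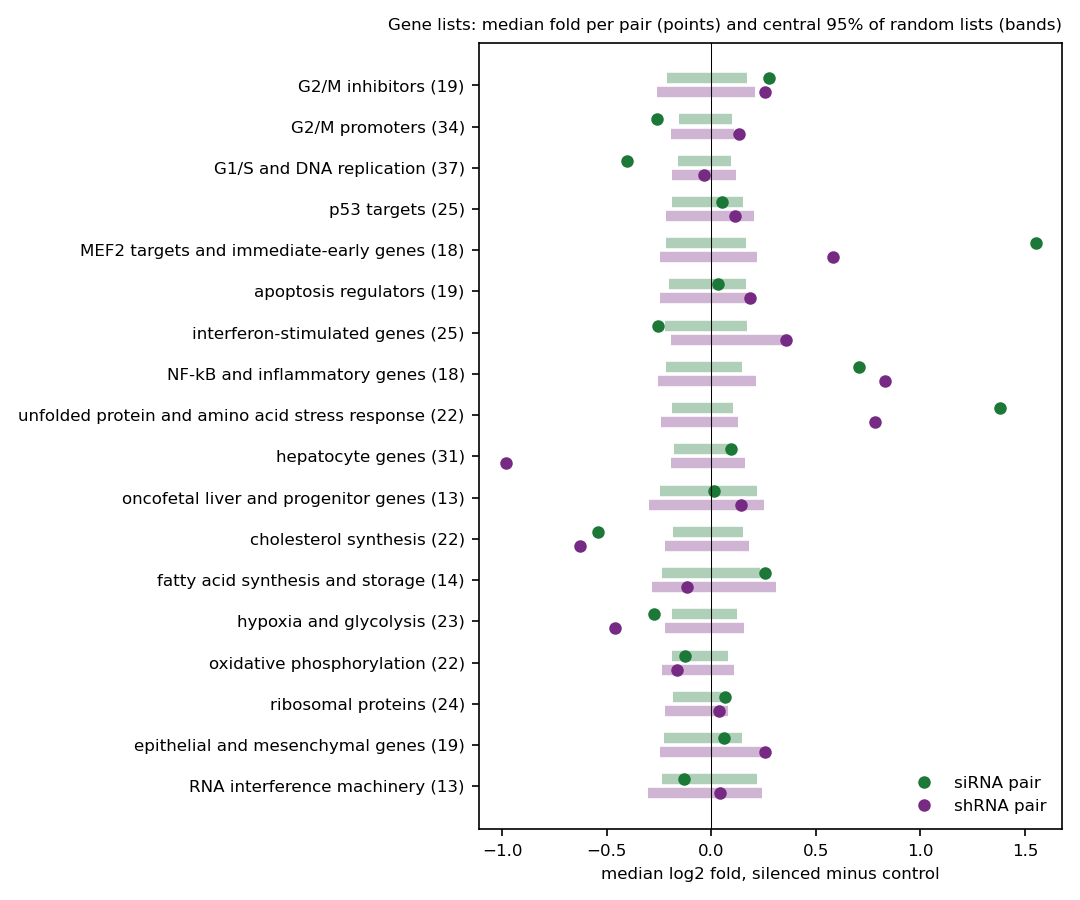
Median log2 fold (horizontal axis, silenced minus control) of each gene list with at least 10 measured members in the siRNA pair (green) and the shRNA pair (purple), beside bands that hold the central part of 10000 random lists of the same size and expression. The stress list lies at 1.38 and 0.78 and cholesterol synthesis at −0.54 and −0.63, outside the bands in both pairs, while the shRNA medians of G1/S genes (−0.04) and ribosomal proteins (0.04) change sign under normexp and quantile normalisation, and the latter with array medians too.

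Hepatocyte genes, the secreted plasma proteins and enzymes of liver, had a median of −0.98 in the shRNA pair, with 20 of 31 measured members at least 1.5-fold lower and 2 higher, below all random lists, and 23 of the 31 were above background on the MEF2D shRNA array. Their median was 0.10 in the siRNA pair, with 4 members at least 1.5-fold higher and 2 lower. APOC3 and APOH, apolipoproteins of the plasma, had −2.56 and −1.85 after shRNA and −0.32 and −0.27 after siRNA. Limma passed 0 members over all genes or adjusted over the list alone (lowest p 0.130), and the difference between the methods was not tested. With normexp the shRNA median was −0.66.

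The side comparison of lentivirus with transfection compared both shRNA arrays with both siRNA arrays. Each method had 1 slide, and its control and silenced arrays stood in as replicates. The SE and p-values of this term leave out variation between slides and between rounds of culture, so they do not show an effect of delivery method. AFP, the fetal liver protein used as a marker of hepatocellular carcinoma, was lower on the shRNA arrays by a log2 difference of −9.81 (limma, SE 0.48, adjusted p 0.00180), with levels of 6.67 and 6.53 on the siRNA arrays and −2.26 and −4.14 on the shRNA arrays. GPC3, another such marker, had −6.05, the bile duct keratin KRT19 −4.90 (−3.08 with normexp), APOC3 −4.93 and GC −7.02. TTR, SERPINC1, HP, AHSG and ALB, plasma proteins chosen after their values were seen, had −8.37, −9.15, −8.47, −7.67 and −4.87. Higher on the shRNA arrays were NR4A3 (3.70), HOXB9 (3.29, and 1.92 with normexp) and the fetal liver factor SALL4 (2.93). The hepatocyte list had a median of −1.83, with 19 members lower and 2 higher by limma over all genes, and the oncofetal list had −0.80, with 7 lower and 3 higher.

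By limma 5873 of 14335 genes differed between the arrays of the 2 methods at an adjusted p under 0.05, 2685 higher and 3188 lower on the shRNA arrays. Because 0 slides held both methods, delivery method, slide, scan and culture cannot be told apart, and this count too leaves out variation between slides. The control arrays had a Pearson r of 0.885 across 12030 genes and 3622 genes (30.1%) at least 2-fold apart, while r was 0.984 within the siRNA pair and 0.975 within the shRNA pair. In the deposited table, which moved the median gene by −0.23 between the slides, 1949 genes were higher and 4452 lower. The same shift was 0.07 in the main values, 0.10 with normexp, 0.20 with array medians and 0.12 with quantile normalisation, and the hepatocyte median stayed between −2.07 and −1.13.

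**Figure D4:**
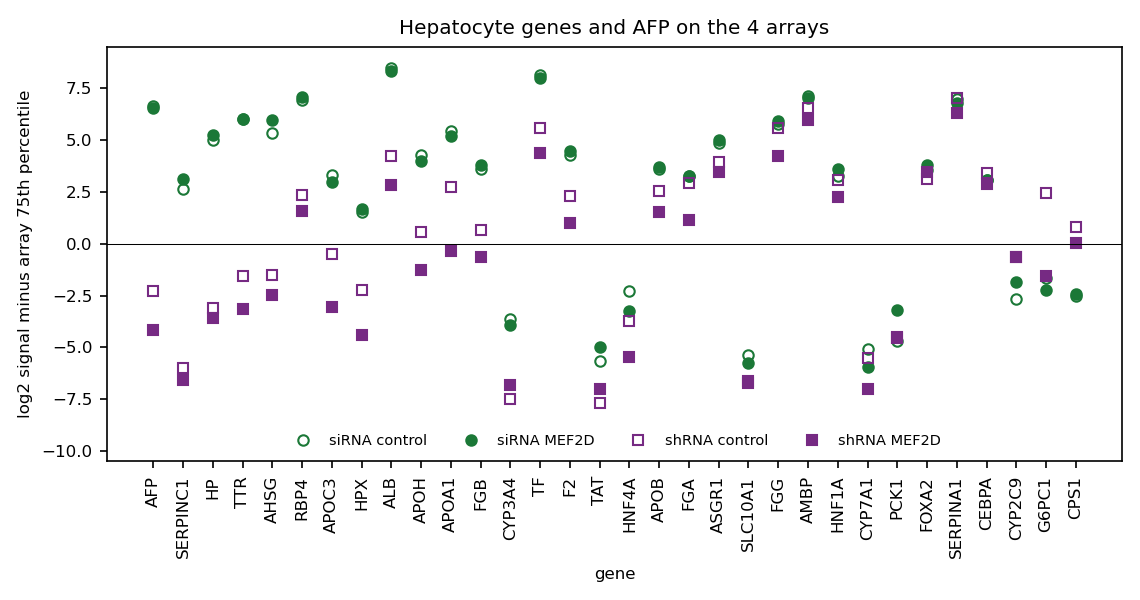
Level of each measured hepatocyte gene and of AFP (vertical axis, log2 signal minus the array's 75th percentile) on the control (open) and MEF2D-silenced (filled) arrays of the siRNA pair (green circles) and the shRNA pair (purple squares). AFP lies at 6.67 and 6.53 on the siRNA arrays and at −2.26 and −4.14 on the shRNA arrays, while G6PC1 is highest on the control lentivirus array.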

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

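All tests in this part were chosen after the result they measure had been seen, and the bounds for scaling of hepatocyte genes and for single probes were set again after first values were known.

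LGALS2, a galectin, had a log2 fold of 0.85 after siRNA and −3.21 after shRNA. The metallothionein genes MT1L, MT1E and MT1B had −1.13, −1.17 and −1.13 after siRNA and 2.68, 2.65 and 2.61 after shRNA. These genes stand out because each pair reached 1.5-fold in the opposite direction, and the difference was not tested. Among probes without a gene symbol, which no comparison used, 27 were at least 2-fold higher in both silenced arrays and 13 lower in both, of 5777 compared.

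Of 22 stress genes 12, among them ATF3, TRIB3 and STC2, were at least 1.5-fold higher in both silenced arrays, while 5 members were below 0 after siRNA and 4 after shRNA. Scaling as the whole cause is argued against by the lowest list median over the main values and 4 other scalings, 0.74 (spread 0.09). Faults of single probes are argued against in the siRNA pair, where 8 other probes of the members had a median fold of 0.89 (spread 0.16), and stay open in the shRNA pair, where it was 0.38 (spread 0.20) against a bound of 0.3. MEF2D silencing and another difference between the cultures cannot be told apart, with 1 culture per group and a MEF2D fold of −0.089 in the shRNA pair, and a wrong label stays open, untested. A biological response to silencing may remain, as a hypothesis only.

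Some very high folds rested on 1 spot each. With spots marked for their local background kept, 3 of 3 genes at least 16-fold higher in the shRNA pair, CFP (8.17), IRF2 (7.99) and ATAD2 (5.93), named after their values were seen, lay on such spots at 1 corner of the slide, although such marks cover 0.413% of the array, so dirt or damage at the corner of the slide may explain them. Other probes of IRF2 and ATAD2 gave −0.26 and −0.02, and the 3 spots were left out of the comparisons. Around the RPRM spot of the siRNA pair 2 of 33 neighbours were at least 4-fold higher, more than around most spots, since 4.34% of spots had as many, but 28.2% of the 337 spots that were themselves at least 4-fold higher did too. The scanner software marked neither the RPRM spot nor its background (0 marks), unlike the 3 corner spots, and no other RPRM probe exists on the array, so dirt or damage beside the spot could account for the value of RPRM but a real difference stays open as well.

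Of 31 measured hepatocyte genes 19 were lower and 2 higher on the shRNA arrays than on the siRNA arrays (limma). Scan brightness or scaling is argued against as the whole cause, since the list median over the main values and 4 other scalings was −1.13 at its highest (spread 0.19). Faults of single probes are argued against by 12 other probes of 9 members, with a median of −1.06 (spread 0.34). Lentiviral delivery cannot be told apart from another cell stock, culture, slide or labelling round, because 0 slides hold both methods and the difference of −1.83 is between the slides. That the cells on both slides are Huh7 rests on the sample titles and was not tested. For scaling and probes the bound was −0.5, and for scaling it had first been −1, which the value passes by less than its spread.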

How the results depend on the processing

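In this part, keeping spots marked for their local background alone was chosen after the data had been seen. Apart from single-pair values of named genes, 368 values under alternatives stayed within a bound and 50 moved beyond it, and the cause was not tested unless stated. The bound was the SD of random list medians for lists and the scanner standard error for MEF2D. For gene counts it was a ratio of 1.5 to the main count, and for correlations a difference of 0.1.

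Normexp with quantile normalisation gave 271, 399 and 57 genes at least 2-fold different (siRNA, shRNA, both), its offset of 50 pulling folds of dim genes to 0 by construction. List medians that moved with it were, in the siRNA pair, G2/M inhibitors 0.11, immediate-early genes 1.24, NF-kB genes 0.55 and fatty acid synthesis 0.13. In the shRNA pair they were MEF2 family 0.0061, immediate-early genes 0.41, NF-kB genes 0.61, fibroblast markers −0.023, hepatocyte genes −0.66, hypoxia −0.36, interferon-stimulated genes 0.074, leukocyte markers −0.046, oxidative phosphorylation −0.073 and ribosomal proteins −0.043. Quantile normalisation gave shRNA medians of −0.0077 for fibroblast markers and 0.13 for interferon-stimulated genes, and the stress list after siRNA had 1.47 in the deposited table.

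Without a filter on dim probes the counts were 1404, 2028 and 244 and the correlation 0.13, since genes near background enter. The NF-kB and hepatocyte medians were 0.59 and 0.021 after siRNA. In the shRNA pair endothelial markers had 0.66, epithelial and mesenchymal genes 0.47, hepatocyte genes −0.81 and leukocyte markers 0.32. A 1.5-fold threshold, which admits smaller folds, gave 2279, 2639 and 555 genes.

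With the mean of a gene's probes the siRNA medians were −0.47 for G1/S genes, 0.14 for apoptosis regulators and −0.047 for endothelial markers. The shRNA medians were 0.30 for endothelial markers, 0.45 for epithelial and mesenchymal genes, −1.15 for hepatocyte genes and 0.30 for p53 targets. List means in place of medians gave, after siRNA, 1.67 for immediate-early genes, 0.80 for NF-kB genes, 0.23 for apoptosis regulators, 0.18 for p53 targets and 1.59 for stress genes, and after shRNA 0.67 for NF-kB genes, 0.40 for apoptosis regulators, −0.36 for hypoxia and 0.90 for stress genes. An intensity trend in eBayes gave 1 gene for silencing, ATF3.

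With each pair left out in turn, 23 of 129 named genes had opposite signs in the pairs, among them 6 of the 74 with a mean of at least 2-fold: AGBL2 from −2.22 to 0.18, HS3ST5 from −2.95 to 0.64, STON1 from −3.47 to 0.79 and TCN1 from −2.70 to 0.63 (without the shRNA pair, then without the siRNA pair), and LGALS2 from 0.85 to −3.21 and TMEM190 from −0.16 to 2.62. STON1, HS3ST5 and TCN1 were above background on neither shRNA array, so their sign there carries no information. AGBL2 after shRNA and TMEM190 after siRNA were each smaller than their scanner standard error of 0.23, and the latter was 0.034 with normexp. For the other named genes leaving a pair out shows only the sign, since 1 pair has no spread. MEF2D stayed between −0.36 and −0.25 in the siRNA pair and between −0.29 and −0.01 in the shRNA pair. The method count stayed between 3991 and 6402.

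A slide block was not run, because it equals the method term. Signal over background limits the shRNA pair most, with 62.2% of spots above background on its silenced array and 12252 genes compared against 14023. The tolerance of 0.1 for a moved correlation was set after the data had been seen.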

Other observations

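In this part, the count of genes above background on the arrays of 1 method alone was chosen after the values were seen. Interferon-stimulated genes had a median of −0.26 after siRNA and 0.36 after shRNA over 25 measured members, the latter 0.074 with normexp and 0.13 with quantile normalisation, and 16 members were above background on the MEF2D shRNA array. There was 1 member at least 1.5-fold higher in both pairs, which was IRF1, an interferon-induced transcription factor, at 0.98 and 1.31 (0.77 and 0.67 with normexp). USP18, a brake on interferon signalling, had −0.15 and 0.78, the latter 0.51 with normexp. Apoptosis regulators had medians of 0.03 and 0.19 and means of 0.23 and 0.40 over 19 members. The siRNA median was higher with the mean of a gene's probes. Limma passed 1 adjusted over the list alone, PMAIP1, the BH3-only protein NOXA (2.42 and 1.54, p 0.0494). BIK, another BH3-only gene, had 0.61 and 1.75, the latter 0.83 with normexp, and BIRC3, a caspase inhibitor, 0.43 and 1.96. Epithelial and mesenchymal genes had medians of 0.06 and 0.26 over 19 members, the latter higher without a filter on dim probes and with the mean of a gene's probes. Among them CLDN1, a tight junction gene, was at 0.91 and 1.29 and SNAI1 at −0.25 and 1.15. For the interferon and epithelial lists limma passed 0 members adjusted over the list alone (lowest p 0.151 and 0.147), and over all genes 0 of the 3 lists.

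Genes of fatty acid synthesis and storage had medians of 0.25 (0.13 with normexp) and −0.12 over 14 members. FASN, fatty acid synthase, was at −0.28 and −1.55, the latter −0.97 with normexp, and GPAM, which starts triglyceride synthesis, at 1.12 and 0.59. Oxidative phosphorylation genes had −0.13 and −0.16 (−0.073 with normexp) over 22 members, with percentiles of 14.4 and 12.5 among random lists. Ribosomal proteins had 0.06 and 0.04 over 24 members, where the shRNA median became negative under normexp, array medians and quantile normalisation. RNA interference machinery had −0.13 and 0.04 over 13 members. Oncofetal genes had 0.01 and 0.14 over 13 members, where the siRNA median became negative under quantile normalisation and in the deposited table. Limma passed 0 members of these 5 lists over all genes or adjusted over the list alone.

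Well above background on the control siRNA array were 6 of 12 fibroblast and stellate, 7 of 11 leukocyte and 5 of 9 endothelial markers on the array design, and on the control lentivirus array 4, 5 and 2. The levels of THY1, CD79A and LYZ on the control siRNA array were 2.22, 2.57 and 1.27, above the 75th percentile of that array. Of fibroblast and stellate markers 6 were measured, with medians of −0.21 and 0.45, the latter negative under normexp and quantile normalisation. Leukocyte markers had −0.03 and −0.40 (−0.046 with normexp) over 6 members, and the latter turned positive without a filter on dim probes. They were lower on the shRNA arrays by a median of −2.07 (−1.02 with normexp), with CD68 at −4.01 and LYZ at −1.87. Endothelial markers had −0.39 and −0.30 over 4 members (−0.12 and −0.080 with normexp). Their shRNA median turned positive without a filter on dim probes and with the mean of a gene's probes, which also brought the siRNA median closer to no change. Limma passed 0 members of these lists for silencing, over all genes or adjusted over the list alone. Genes above background on both siRNA arrays and neither shRNA array numbered 1349, against 147 the other way round. The lowest level called above background was −5.95 and −6.08 on the siRNA arrays (control, silenced) and −5.43 and −4.77 on the shRNA arrays. Weaker detection on the shRNA arrays could thus add to such an imbalance. How much of it this gives was not counted, and the counts do not show genes switched off.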
